A study of Mus musculus with 10 samples.

How the data were processed

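RNA was sequenced from 10 livers of C57BL/6 mice aged 24 weeks, 5 WT and 5 Fbp1-deleted, with group and replicate taken from the sample titles. Per the labels' protocols, a column kit gave total RNA of the frozen tissue, and an Illumina mRNA library that does not keep the strand was made of each sample. Per the series' design text, fragments were read from both ends. The series' design text speaks of 5 biological replicates per group. The replicate numbers differ between the groups, so no samples were paired. No sex, litter, hour of collection, feeding state or batch was given in the sources used here.

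The deposited table holds estimated counts per gene, 1 column per liver. The submitters' processing notes name CASAVA, Salmon and the build GRCm38, without versions. The table's own name points to Salmon estimates summed to genes, but the settings of that step are not given in the sources used here, so whether the counts were adjusted for transcript length is open. The design text also describes STAR alignment with featureCounts and DESeq2 in R 3.3.3, a route that the table's name does not mention. Salmon divides reads between similar transcripts by a model, so counts of close paralogs and of overlapping genes carry an error that replicates do not show. The library does not mark strand, so a gene and its antisense partner cannot be told apart. Of the 156 genes named, 51 overlap the span of another annotated gene.

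All deposited estimated counts were whole numbers (0 values were not whole), so no rounding was needed. The table has 53392 genes, of which 52175 matched the GENCODE M21 annotation of GRCm38 by identifier and version and 1180 by identifier with another version. The remaining 37 held 0.0012% of all counts and were kept under their identifiers. Counts were 0 in all libraries for 19697 genes. Totals were between 17778395 and 23894812 counts per library. Mitochondrial transcripts took between 4.24% and 6.47% of a library. Libraries were checked for duplicates, and the smallest chi-square per degree of freedom within a group was 16.6, where the same library sequenced again would give about 1.

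Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood F test compared Fbp1-deleted with WT (~ group, no covariate). Adjusted p is Benjamini-Hochberg over the 15392 genes tested, with a threshold of 0.05. The standard error is the size of the fitted log2 change divided by the square root of F. CPM uses TMM-scaled library sizes. The biological coefficient of variation was 0.235.

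Gene lists (53) covered carbohydrate, lipid, bile acid and nitrogen metabolism, mitochondria, stress, inflammation, cell types, zonation, sex bias, other tissues and the clock. Lists with at least 5 measured members (51) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. The members named were those with the 4 smallest adjusted p of a list, members whose direction differed from their list, Fbp1, Fbp2, Pck1, G6pc, Acta2, Col1a1, Cdkn1a, Cdkn2a and Afp, sex chromosome transcripts, and the 3 genes with the largest mean share of counts per group. In each direction the 12 genes with the largest change were also named, among those called, with an average log2 CPM of at least 1 and no overlap between groups. Unnamed and provisional gene symbols were skipped there. Il6 and Tnf, and in the closing section Timd4 and the members of the gene families and of the growth hormone pathway, stand outside this rule. Il6, Tnf, Timd4 and the family members were chosen after their values were seen. Some members that the rule names are not reported here.

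The lists, the naming rule, the tests and the following alternatives were fixed before the data were examined. For genes the alternatives in scaling and filtering were edgeR's relative log expression (RLE) factors, upper quartile scaling, library totals alone, no filter and a stricter filter. Alternative tests were DESeq2 1.42.0's Wald test, limma-voom, edgeR without robust shrinkage, an adjusted p threshold of 0.01 and a test against a fold of 1.5. The others were 1 surrogate variable from sva 3.50.0, removal of the 8 genes above 1% of a library, and each library left out in turn. For lists they were camera with an estimated correlation, fry, a prior count of 0.5, library totals, RLE factors, the stricter filter and each library left out. Fits with a clock or leukocyte marker index as a covariate were added after the data were seen, as were the fits without each library for genes outside the naming rule. The annotated transcripts of Fbp1 and Fbp2 were searched in Python 3.11.15 for shared words of 31 bases on either strand, a test also added then.

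The fit was tested on simulated data for the comparison of Fbp1-deleted with WT, drawn for the 15392 genes tested from the real means, dispersions and library sizes, with 200 genes changed. The filter on low counts kept 15017 of the simulated genes, and changed genes that it removed were scored as missed. The fit recovered 28% of genes changed 1.5-fold, 56% at 2-fold, 92% at 4-fold and 90% at 8-fold, and 6 unchanged genes were called, 4.3% of the calls. Many simulated changes of 2-fold or less were therefore missed. The adjusted p also depends on how many genes change, and the real data gave 3178 calls. With only 200 genes changed, the simulated shares may be lower than those in the real data, which were not measured. Of 5 simulated lists raised 1.5-fold all were called, and 0 of 25 unchanged lists. The simulated genes were independent of each other, so that test does not cover correlated genes.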

Results

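The series asked how the loss of Fbp1 changes gene expression in the mouse liver. Fbp1 encodes fructose bisphosphatase, an enzyme of gluconeogenesis that removes a phosphate from fructose bisphosphate. Snap-frozen livers of C57BL/6 mice aged 24 weeks were profiled by RNA sequencing in 2 groups, wild type (WT, n = 5) and mice lacking hepatic Fbp1 (Fbp1-deleted, n = 5). The libraries held between 17778395 and 23894812 estimated reads assigned to genes. The mean depth was 19639013 ± 2389919 reads (SD, n = 5) in WT and 19400659 ± 1541288 reads (SD, n = 5) in Fbp1-deleted liver. Alb, which encodes serum albumin, took the largest share of counts in each library, between 3.47% and 7.05%, followed in the group means by Apoe with Trf in WT and with mt-Co1 in Fbp1-deleted liver. None of these 4 genes passed the test (adjusted p between 0.198 and 0.518, edgeR). Levels are given below as counts-per-million (CPM), mean ± SD over the 5 libraries of a group, and changes as Fbp1-deleted minus WT on the log2 scale with the standard error of the fit (SE).

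Fbp1 transcript fell in all 5 libraries labelled Fbp1-deleted. The gene (ENSMUSG00000069805.10) lies on the minus strand of chromosome 13, from 62864753 to 62888282 in GRCm38, and is protein-coding. Its level was 909.6 ± 119 CPM in WT, with libraries between 778 and 1050, and 9.39 ± 2.38 CPM in Fbp1-deleted liver, with libraries between 7.38 and 13.4. The change was -6.60 (SE 0.19, adjusted p = 6.13e-11, edgeR quasi-likelihood test), or 96.7-fold lower. Fbp2, which encodes the second mammalian fructose bisphosphatase, known chiefly from muscle, moved the opposite way. Fbp2 (ENSMUSG00000021456.8, chromosome 13, 62836877 to 62858422, minus strand) lies 6.3 kb from Fbp1. It rose from 0.317 ± 0.166 to 92.1 ± 11.6 CPM, a change of 8.12 (SE 0.24, adjusted p = 6.13e-11), which was the largest rise among the genes named. The sum of both transcripts in Fbp1-deleted liver was 11.2% of the sum in WT.

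**Figure D1:**
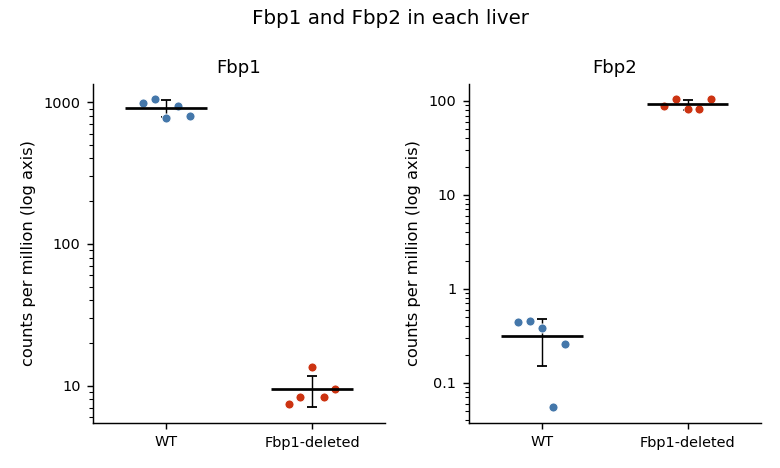
Fbp1 (left) and Fbp2 (right) in each liver, in counts-per-million on a log axis. Points are single libraries and the thick bar with its whiskers is the mean ± SD of the 5 libraries of a group. Fbp1 lies between 778 and 1050 CPM in WT and between 7.38 and 13.4 CPM in Fbp1-deleted liver, and Fbp2 between 81.6 and 104.8 CPM in Fbp1-deleted liver.

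Of 15392 genes tested, 1636 rose and 1542 fell in Fbp1-deleted liver, 20.6% of the genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was fitted for 443 of the genes that rose and 487 of those that fell. In 13.5% of the genes tested the 5 values of a group lay wholly above those of the other, where chance gives 0.79%. The first principal component held 37.6% of the variance and parted the genotypes, with WT libraries between -46.6 and -18.2 and Fbp1-deleted libraries between 6.4 and 54.5. Fbp1-deleted replicate 8 had the score of 6.4, and the other 4 lay at 35.3 or above. The split between directions depended on the scaling. Genes that rose were 51.5% of the calls with TMM factors, 40.3% with upper quartile scaling and 37.7% with library totals alone, and no call changed sign. Leaving out Fbp1-deleted replicate 9 left 1066 genes higher, and leaving out Fbp1-deleted replicate 6 left 1086 higher and 1019 lower.

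After Fbp2, the largest rises among genes whose groups did not overlap were those of Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, by 46.6-fold to 223 ± 134 CPM, the adrenergic receptor Adra2a, by 43.5-fold to 7.51 ± 6.24 CPM, and the leptin receptor Lepr, by 29.2-fold to 306.5 ± 94.2 CPM. The orphan nuclear receptors Nr4a2 and Nr4a3 rose by 4.36 (SE 0.39) and 3.55 (SE 0.73). Fst, which encodes follistatin, rose by 4.03 (SE 0.58), Ddit4, an inhibitor of mTORC1, by 3.87 (SE 0.45), and Igfbp1, an insulin-repressed binding protein for insulin-like growth factors, by 3.59 (SE 0.62) to 1083 ± 677 CPM. Cend1, Fam222a and Enc1 completed the 12 largest rises, with changes of 3.69, 3.59 and 3.31. Adjusted p for the 12 genes lay between 6.13e-11 and 0.00668. Ppp1r3g and Fst overlap another annotated gene, so their counts in this library type without strand are uncertain. The change of Nr4a3 was 2.78 without Fbp1-deleted replicate 10, which held 9.70 CPM against 0.910 to 4.61 in the other 4, and that of Adra2a was 6.07 without WT replicate 2.

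After Fbp1, the largest fall was that of Nr0b2, which encodes the repressor SHP of bile acid synthesis, from 16.7 ± 7.13 to 1.14 ± 1.05 CPM, a change of -3.84 (SE 0.57). The guanylate-binding protein gene Gbp11 fell by 3.15 on the log2 scale (SE 0.35), the liver transcription factor Onecut1 by 2.98 (SE 0.53) and Socs2, a target of STAT5, by 2.70 (SE 0.47). The thymidine kinase gene Tk1 fell from 54.0 ± 14.8 to 9.91 ± 2.87 CPM, and Angptl8, an insulin-induced inhibitor of lipoprotein lipase, from 80.9 ± 52.4 to 14.2 ± 6.04 CPM. Cyp2g1, Rnf186, Col9a3, S1pr5 and the interferon-induced Xaf1 fell by 2.70, 2.65, 2.40, 2.37 and 2.31 on the log2 scale. Adjusted p for these 11 genes lay between 1.23e-05 and 0.0147. Single libraries moved 3 of these values: the change of Onecut1 was -2.31 without WT replicate 4, that of Cyp2g1 -1.93 without WT replicate 5 and that of Nr0b2 -4.53 without Fbp1-deleted replicate 8. Gbp11 belongs to a family of similar genes, and Onecut1, Angptl8, Tk1 and Col9a3 overlap another annotated gene, so their counts in this library type without strand are uncertain.

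Of 53 gene lists, 51 had 5 or more measured members and were tested with camera at a preset correlation of 0.01 between genes. By that test 11 lists were higher and 12 lower in Fbp1-deleted liver. With a correlation estimated from each list, 0 lists passed (camera, 9 at an unadjusted p under 0.05), while fry, which tests whether a list moves one way without comparing it with other genes, called 25. Among these were 5 lists that camera did not call, namely glycogen metabolism (adjusted p = 0.00052, fry), the pentose phosphate pathway (0.01), the urea cycle (0.0061), p53 targets (0.0016) and T cell markers (0.036). Below, a list is called or not by camera at the preset correlation. Other splits of the same 10 libraries into groups of 5 called up to 25 lists. The counts of single genes that rose or fell within each list do not rest on camera. They are given below over all genes tested and, beside that, adjusted over the list alone.

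Genes of glucose production rose. In the gluconeogenesis list, from which Fbp1 was left out but which holds Fbp2, 9 of 16 members rose and 1 fell (10 and 1 adjusted over the list alone). G6pc, the catalytic subunit of glucose-6-phosphatase, rose from 281 ± 109 to 1976 ± 185 CPM, a change of 2.81 (SE 0.22, adjusted p = 8.49e-06). Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase, rose from 3401 ± 963 to 8611 ± 812 CPM, and the coactivator Ppargc1a from 10.2 ± 0.184 to 64.9 ± 27.1 CPM. The alanine aminotransferase gene Gpt fell by 0.79 on the log2 scale (SE 0.16, adjusted p = 0.00341). The list was called higher (median 0.58, adjusted p = 1e-04, camera), with adjusted p = 0.15 with an estimated correlation.

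Several glycolytic genes and most listed targets of the carbohydrate-responsive factor ChREBP rose in the same livers. The phosphoglucose isomerase gene Gpi1 rose by 1.64 (SE 0.12), Eno1 by 0.89 (SE 0.11) and Pklr, the liver pyruvate kinase, by 0.86 (SE 0.13). Over the glycolysis list 11 of 25 members rose and 3 fell (11 and 4 adjusted over the list alone; median 0.34, adjusted p = 0.0096 with camera, adjusted p = 0.34 with an estimated correlation). Of 13 ChREBP targets, 9 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.86, adjusted p = 5e-06 with camera, adjusted p = 0.15 with an estimated correlation). They included Tkfc, which phosphorylates glyceraldehyde from fructose, with a change of 1.91 (SE 0.18), and Txnip, an inhibitor of glucose uptake, with 1.49 (SE 0.18). The glycolysis list was not called without Fbp1-deleted replicate 8 (adjusted p = 0.07), and its mean log2 CPM in replicate 10 (5.86) lay below the highest WT library (5.89).

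Members of the glycogen and pentose phosphate lists went both ways, and camera called neither list. In the glycogen list 6 of 16 members rose and 2 fell (7 and 3 adjusted over the list alone; median 0.16, adjusted p = 0.063, camera). Camera called it with library totals (adjusted p = 0.044) and without WT replicate 2 or 3 or Fbp1-deleted replicate 7, 9 or 10 (adjusted p between 0.038 and 0.048). Beside Ppp1r3g, the liver glycogen phosphorylase Pygl rose by 0.95 (SE 0.09), the glycogen synthase Gys2 by 1.30 (SE 0.18) and Stbd1 by 0.78 (SE 0.13). In the pentose phosphate list 3 of 11 members rose and 1 fell (3 and 2 adjusted over the list alone; adjusted p = 0.36, camera), with Pgd at 1.62 (SE 0.13) and Rpia at 1.24 (SE 0.17). The median of that list was -0.04 and its mean 0.19.

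**Figure D2:**
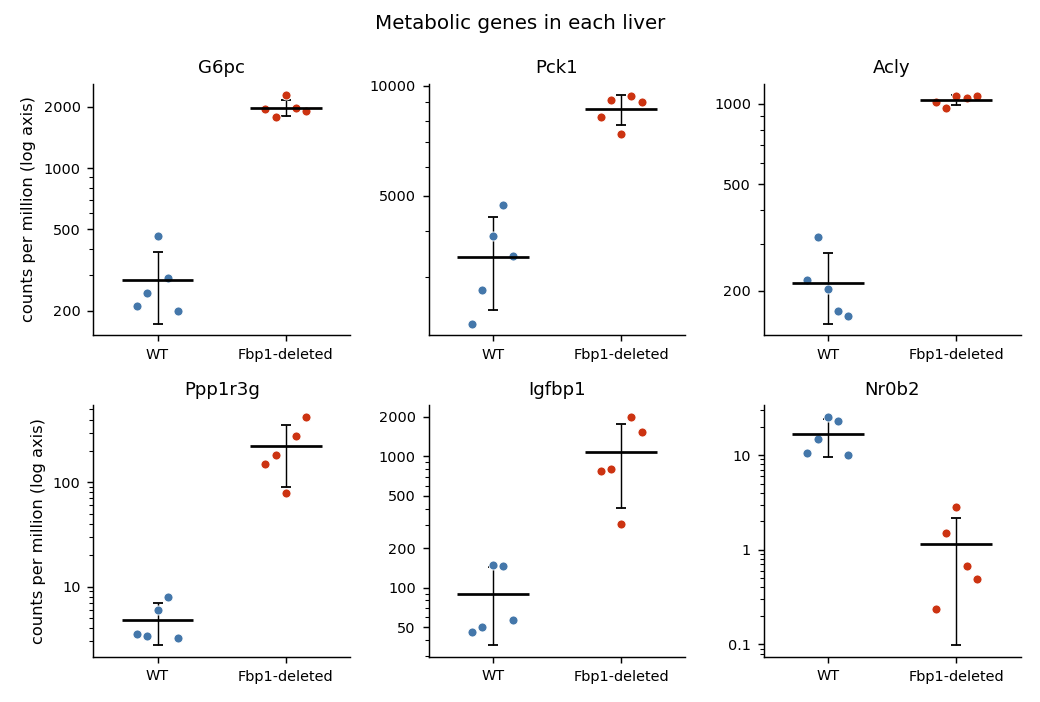
Level of 6 metabolic genes in each liver, in counts-per-million on log axes. Points are single libraries and the thick bar with its whiskers is the mean ± SD of the 5 libraries of a group. G6pc, Pck1, Acly, Ppp1r3g and Igfbp1 are higher and Nr0b2 lower in Fbp1-deleted liver, with all 5 values of one group above those of the other in each panel.

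Several genes of fatty acid synthesis and lipid droplets rose. Acly, which makes cytosolic acetyl-CoA from citrate, rose from 213 ± 62.9 to 1032 ± 45.4 CPM, a change of 2.27 (SE 0.17, adjusted p = 2.78e-06), and the fatty acid elongase Elovl5 from 250.0 ± 11.1 to 799 ± 50.3 CPM. Me1 and Acaca rose by 1.64 (SE 0.15) and 1.52 (SE 0.14), while the desaturase Fads1 fell by 0.76 on the log2 scale (SE 0.16). Over the lipogenesis list 7 of 16 members rose and 2 fell (7 and 2 adjusted over the list alone; median 0.52, adjusted p = 0.0011 with camera, adjusted p = 0.25 with an estimated correlation). Of 23 genes of triglyceride storage 9 rose and 2 fell (11 and 2 adjusted over the list alone; median 0.29, adjusted p = 0.0027 with camera, adjusted p = 0.25 with an estimated correlation). The droplet protein genes Cidec and Plin2 rose by 2.72 (SE 0.39) and 0.83 (SE 0.14), the lipase Pnpla2 by 0.70 (SE 0.11), and the acyltransferase Dgat2 fell by 0.53 on the log2 scale (SE 0.12).

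The lists for oxidation of fatty acids and for ketone bodies held fewer calls. In the list of fatty acid oxidation and PPARA targets 5 of 26 members rose and 1 fell (6 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.12, camera), among them Etfdh at 0.59 (SE 0.13), Hsd17b4 at 0.45 (SE 0.11) and Acaa1a at -0.53 (SE 0.12). Camera called that list without Fbp1-deleted replicate 10 (adjusted p = 0.049). In ketone body synthesis 2 of 6 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.36, adjusted p = 0.031 with camera, adjusted p = 0.27 with an estimated correlation). Among them the monocarboxylate carrier Slc16a1 rose by 1.11 (SE 0.12). The ketone list was not called without Fbp1-deleted replicate 8 (adjusted p = 0.078).

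Several cholesterol synthesis genes were lower. Of 25 genes of cholesterol synthesis and SREBP2 targets 8 fell and 1 rose (16 and 1 adjusted over the list alone). Ebp fell by 0.45 on the log2 scale (SE 0.09, adjusted p = 0.00461) and Pmvk by 0.88 (SE 0.20, adjusted p = 0.0106), while Hsd17b7 rose by 0.56 (SE 0.14). The list was called lower (median -0.45, adjusted p = 2e-04, camera), with adjusted p = 0.52 with an estimated correlation, and fry did not call it (adjusted p = 0.083). Its mean log2 CPM in Fbp1-deleted replicates 8 and 9 (6.18 and 6.27) lay within the WT range (5.91 to 6.62).

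Bile acid genes went both ways. Cyp8b1, the sterol hydroxylase that sets the share of cholic acid, rose from 91.9 ± 9.79 to 583.5 ± 155 CPM, a change of 2.67 (SE 0.17, adjusted p = 8.22e-07), and the phospholipid exporter Abcb4 rose by 1.09 (SE 0.16), beside the fall of Nr0b2. Of 18 members 3 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.05 and a mean of -0.02, while camera placed the list upward without calling it (adjusted p = 0.95).

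Genes of the tricarboxylic acid cycle rose, and those of the respiratory chain mostly did not pass. Of 17 cycle genes 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.30, adjusted p = 0.00035 with camera, adjusted p = 0.25 with an estimated correlation). Fh1, the fumarate hydratase, rose by 1.51 (SE 0.17), Idh3a by 0.86 (SE 0.14) and Dlst by 0.55 (SE 0.09). Of 22 nuclear-encoded genes of oxidative phosphorylation 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.03, adjusted p = 0.25, camera), namely Cycs at 0.72 (SE 0.14) and Ndufs1 at 0.36 (SE 0.09). Of 13 mitochondrially encoded transcripts 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.08, adjusted p = 0.1, camera), namely mt-Nd5 at 0.73 (SE 0.13), mt-Nd1 at 0.61 (SE 0.13) and mt-Nd6 at 0.54 (SE 0.13). The spans of mt-Nd5 and mt-Nd6 overlap, so reads from the pair cannot be told apart there. Camera called the mitochondrially encoded list without WT replicate 1 (median 0.22, adjusted p = 0.0094).

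In nitrogen metabolism, 4 of 8 urea cycle genes rose and 1 fell (4 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.12, camera). Slc25a15, the mitochondrial ornithine carrier, rose by 1.20 (SE 0.18) and Asl by 0.79 (SE 0.11), and Nags fell by 0.58 on the log2 scale (SE 0.13). In amino acid catabolism 9 of 28 members rose and 5 fell (10 and 8 adjusted over the list alone). Kynu of tryptophan breakdown rose by 1.65 (SE 0.17) and Hgd of tyrosine breakdown by 1.04 (SE 0.13), while Prodh of proline breakdown fell by 1.40 (SE 0.15) and Dbt of the branched-chain ketoacid complex by 0.97 (SE 0.14) on the log2 scale. The median of that list was -0.12 and its mean 0.08, and it was not called (adjusted p = 0.89, camera).

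Genes that respond to fasting rose. Of 19 members 13 rose and 1 fell (14 and 2 adjusted over the list alone; median 1.07, adjusted p = 1.1e-06 with camera, adjusted p = 0.27 with an estimated correlation). G6pc, Ppargc1a, Txnip and Pck1 passed with the smallest p. The metallothionein gene Mt1 fell by 1.48 on the log2 scale (SE 0.38, adjusted p = 0.0217), and its call was lost without Fbp1-deleted replicate 6 or replicate 10 (adjusted p = 0.052 and 0.0502) and without the filter on low counts (0.0683). G6pc and Txnip also stand in the ChREBP list, and G6pc, Ppargc1a and Pck1 in the gluconeogenesis list, so these lists are not separate evidence.

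Genes of the unfolded protein response of the endoplasmic reticulum rose together. Of 19 members 16 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.99, adjusted p = 6e-06 with camera, adjusted p = 0.41 with an estimated correlation). The chaperone Hspa5 rose from 353.5 ± 93.2 to 1449 ± 809 CPM, a change of 2.04 (SE 0.44, adjusted p = 0.011), Hsp90b1 by 1.06 (SE 0.24), Sel1l by 0.99 (SE 0.23) and the sensor Ern1 by 0.84 (SE 0.16). Xbp1, the transcription factor of the pathway, fell by 0.52 on the log2 scale (SE 0.15, adjusted p = 0.0283), a call lost without Fbp1-deleted replicate 6 or replicate 10 (adjusted p = 0.0575 and 0.062). The Fbp1-deleted livers varied widely: Hspa5 stood at 1873 to 2133 CPM in replicates 6, 7 and 9 but at 511.9 and 630.0 CPM in replicates 8 and 10, against at most 471.8 CPM in WT, and the list's mean log2 CPM in those 2 libraries (7.30 and 7.18) lay within the WT range (6.58 to 7.33).

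Other stress programmes moved less evenly. Of 19 genes of the integrated stress response and ATF4 targets 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.039 with camera, adjusted p = 0.48 with an estimated correlation). Fgf21, a hormone of the fasted liver, rose from 1.90 ± 0.640 to 11.8 ± 7.44 CPM, Sesn2 by 0.87 (SE 0.18), and the lipoprotein receptor Vldlr fell by 1.52 on the log2 scale (SE 0.31). Fgf21 stood between 16.4 and 18.6 CPM in Fbp1-deleted replicates 6, 7 and 9 but at 4.51 and 2.98 CPM in replicates 8 and 10, and the list's mean log2 CPM in replicate 8 (3.48) lay within the WT range (3.24 to 3.56). That list was not called without WT replicate 1 or 2 or without Fbp1-deleted replicate 7 or 9 (adjusted p between 0.056 and 0.063, camera). Nor was it called with the stricter filter on low counts (adjusted p = 0.064, camera), and its median was 0.24 without WT replicate 1. Of 21 p53 targets 8 rose and 1 fell (9 and 3 adjusted over the list alone; median 0.38, adjusted p = 0.054, camera), with Eda2r at 1.95 (SE 0.42), Ei24 at 0.59 (SE 0.12) and Bbc3 at -1.35 (SE 0.25). The p53 list was called with library totals (adjusted p = 0.035), with the stricter filter on low counts (0.038) and without WT replicate 1 or 2 or Fbp1-deleted replicate 8 or 9 (adjusted p between 0.038 and 0.046). Cdkn1a, the p21 inhibitor of the cell cycle, rose by 2.88 (SE 0.69, adjusted p = 0.0198) with overlapping groups, and its call was lost without WT replicate 5 (adjusted p = 0.0512). Of 22 HIF targets 5 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.25, camera), with Egln3 at 1.16 (SE 0.15) and Bnip3 at -0.51 (SE 0.11). Of 17 immediate early and heat shock genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; median 0.31, adjusted p = 0.39, camera), with Jun at 1.86 (SE 0.43), Ier2 at -1.14 (SE 0.13) and Ier3 at -0.83 (SE 0.22).

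Interferon-stimulated genes fell together. Of 27 members 20 fell and 0 rose (26 and 0 adjusted over the list alone; median -1.02, adjusted p = 3.1e-13 with camera, adjusted p = 0.25 with an estimated correlation). Mx2, an antiviral GTPase, fell from 7.76 ± 1.53 to 2.24 ± 0.374 CPM, a change of -1.79 (SE 0.19, adjusted p = 4.91e-05). The transcription factors Irf7 and Irf9 fell by 1.09 (SE 0.12) and 0.74 (SE 0.09) on the log2 scale and Rtp4 by 1.46 (SE 0.19). The mean log2 CPM over the list lay between 3.15 and 3.89 in WT libraries and between 2.33 and 2.72 in Fbp1-deleted libraries. Of 18 measured chemokines and cytokines 7 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.43, adjusted p = 0.00094 with camera, adjusted p = 0.18 with an estimated correlation). Ccl9 fell by 1.53 (SE 0.21), Cxcl10 by 1.51 (SE 0.33), Csf1 by 0.84 (SE 0.19) and Cxcl12 by 0.56 (SE 0.11) on the log2 scale. Il6 and Tnf lay below the filter on low counts, with 0 and 14 counts in all WT libraries and 10 and 8 in all Fbp1-deleted libraries.

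**Figure D3:**
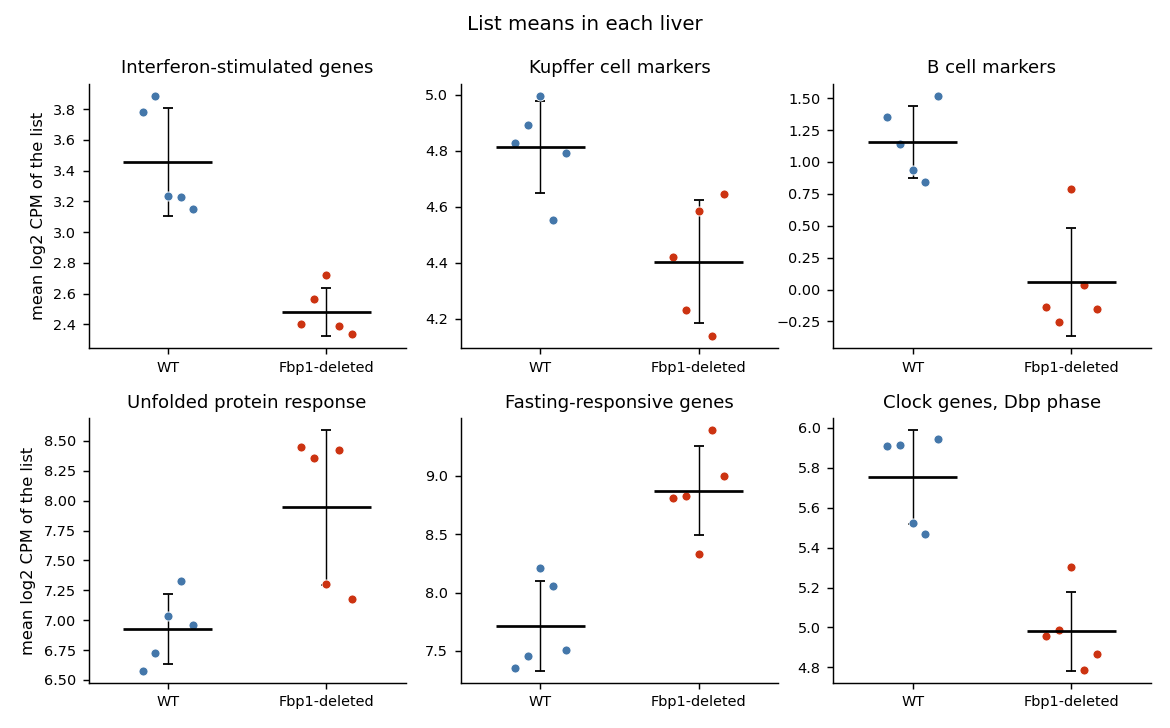
Mean log2 counts-per-million over the measured members of 6 gene lists in each liver. Points are single libraries and the thick bar with its whiskers is the mean ± SD of the 5 libraries of a group. Interferon-stimulated genes lie between 3.15 and 3.89 in WT and between 2.33 and 2.72 in Fbp1-deleted liver, while the unfolded protein response overlaps between the groups.

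Markers of several leukocyte types were lower in the same libraries. Of 11 measured B cell markers 6 fell and 0 rose (9 and 0 adjusted over the list alone; median -1.17, adjusted p = 0.00017 with camera, adjusted p = 0.25 with an estimated correlation), with Pax5 at -2.34 (SE 0.59, or -3.28 without Fbp1-deleted replicate 8) and Cd79a at -1.23 (SE 0.32), both below 2 CPM on average. Of 16 Kupffer cell markers 9 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.46, adjusted p = 2e-04 with camera, adjusted p = 0.36 with an estimated correlation), among them Folr2 at -0.63 (SE 0.14) and C1qb at -0.47 (SE 0.11). Of 21 markers of recruited monocytes and lipid-associated macrophages 5 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.49, adjusted p = 0.0027 with camera, adjusted p = 0.25 with an estimated correlation), with Ly6c2 at -1.27 (SE 0.25) and Tyrobp at -0.60 (SE 0.14). The mean log2 CPM of Kupffer markers in Fbp1-deleted replicates 8 and 10 (4.58 and 4.65) lay within the WT range (4.55 to 5.00), as did that of monocyte markers in replicate 8 (2.03, WT 1.95 to 2.32). Of 13 genes of dendritic cells and MHC class II only Ciita fell, by 0.87 on the log2 scale (SE 0.27, 0 genes adjusted over the list alone), and the list was called (median -0.53, adjusted p = 0.0084 with camera, adjusted p = 0.34 with an estimated correlation). Of 5 measured NK cell markers 2 fell and 0 rose (3 and 0 adjusted over the list alone; median -1.37, adjusted p = 0.031 with camera, adjusted p = 0.27 with an estimated correlation), with Ccl5 at -1.50 (SE 0.35). The NK list was not called without WT replicate 3 or 5 or Fbp1-deleted replicate 8 or 10 (adjusted p between 0.061 and 0.099), with medians from -0.73 without Fbp1-deleted replicate 10, and the call of Gzma, the other NK marker, was lost in 7 of the 10 fits that each left out 1 library, all but those without WT replicate 3 or Fbp1-deleted replicate 7 or 8 (adjusted p between 0.058 and 0.105), and without the filter on low counts (0.0615). The call of Ciita was also lost in 7, all but those without WT replicate 4 or Fbp1-deleted replicate 8 or 10 (adjusted p between 0.0654 and 0.0877), and without the filter (0.084).

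Camera did not call the neutrophil and T cell lists over all 10 libraries. Of 5 neutrophil markers 0 passed (0 adjusted over the list alone; median -0.79, adjusted p = 0.084, camera), with S100a8 at -1.31 (SE 0.45, adjusted p between 0.0232 and 0.041 without WT replicate 1 or Fbp1-deleted replicate 9, with other scaling or filters and with DESeq2), and camera called the list lower without WT replicate 1 or 2 or Fbp1-deleted replicate 9 (adjusted p between 0.019 and 0.048). Of 11 T cell markers only Thy1, which fibroblasts also express, rose, by 0.63 (SE 0.20, 0 genes adjusted over the list alone), and the list had a median of -0.63 (adjusted p = 0.08, camera), with Trbc1 at -0.96 (SE 0.38) and Lck at -0.63 (SE 0.26). The T cell list was called lower by fry (adjusted p = 0.036) and by camera without WT replicate 4 or Fbp1-deleted replicate 6 (adjusted p = 0.015 and 0.02). The call of Thy1 was lost in 8 of the 10 fits that each left out 1 library, all but those without Fbp1-deleted replicate 9 or 10 (adjusted p between 0.0554 and 0.0962), and with upper quartile scaling (0.0761), library totals (0.0781) and limma-voom (0.0552). Of 22 endothelial markers 1 rose and 0 fell (1 and 0 adjusted over the list alone), namely Lyve1 at 0.83 (SE 0.13, adjusted p = 0.00102), while the list was called lower (median -0.29, adjusted p = 0.028 with camera, adjusted p = 0.58 with an estimated correlation, adjusted p = 0.16 with fry). That call was lost without WT replicate 5 or Fbp1-deleted replicate 7, 8 or 9 (adjusted p between 0.05 and 0.07), and the list's mean log2 CPM in Fbp1-deleted replicate 10 (4.09) was above every WT library (3.87 to 4.08).

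Over all genes tested, a few markers of stellate cells and matrix rose and none fell, while genes of senescence went both ways. Of 19 markers of activated stellate cells 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.10, adjusted p = 0.33, camera), with Postn at 0.77 (SE 0.17, adjusted p = 0.00657). Acta2 was at -0.70 (SE 0.36, adjusted p = 0.196) and Col1a1 at 1.35 (SE 0.60, adjusted p = 0.141), with Col1a1 at 37.2 CPM in Fbp1-deleted replicate 8 and between 4.55 and 9.30 CPM in the other 4. Of 16 markers of quiescent stellate cells 3 rose and 0 fell (5 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.21, camera), and of 33 matrix genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.09, adjusted p = 0.13, camera), among them Col12a1 at 1.22 (SE 0.28) and Col5a3 at 1.11 (SE 0.25). Except for Postn, the stellate markers that rose lost their calls without WT replicate 2 or 5 (adjusted p between 0.062 and 0.13). Most of these markers also lost their calls with upper quartile scaling or library totals alone (adjusted p between 0.0514 and 0.123). The matrix list was called higher without WT replicate 3 (adjusted p = 0.046). Of 20 measured genes of senescence and its secretory phenotype 5 rose and 5 fell (5 and 5 adjusted over the list alone; median -0.05, adjusted p = 0.85, camera). Beside Cdkn1a, Tnfrsf1b rose by 1.08 (SE 0.19) and Icam1 fell by 0.75 on the log2 scale (SE 0.17). Cdkn2a lay below the filter on low counts, with 74 counts in all WT libraries and 23 in all Fbp1-deleted libraries, and did not pass where it was tested without the filter (adjusted p = 0.0791).

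Proliferation, tumour and duct markers were mostly outside the calls. Of 28 cell cycle genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.10, adjusted p = 0.39, camera), namely Rrm2, a subunit of ribonucleotide reductase, from 7.83 ± 1.77 to 24.6 ± 4.85 CPM. Of 18 fetal liver and tumour markers 1 rose and 2 fell (1 and 2 adjusted over the list alone; median -0.24, adjusted p = 0.25, camera), with Ly6d at 3.25 (SE 0.48), Sox4 at -0.87 (SE 0.24) and the fetal marker Afp at -0.85 (SE 0.33, adjusted p = 0.084), which passed without WT replicate 4 (-1.01, adjusted p = 0.0378). Of 11 cholangiocyte markers 0 rose and 1 fell (0 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.39, camera).

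Several pericentral genes of the liver lobule fell and several periportal genes rose. Of 19 pericentral genes 6 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.48, adjusted p = 0.00041 with camera, adjusted p = 0.25 with an estimated correlation). Tbx3 fell by 1.71 (SE 0.34), Cyp1a2 by 0.69 (SE 0.14) and Cyp2e1 by 0.48 (SE 0.13) on the log2 scale. Of 19 periportal genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.17, mean 0.75, adjusted p = 0.037 with camera, adjusted p = 0.27 with an estimated correlation), with Etnppl, a lyase of phosphoethanolamine, at 3.01 (SE 0.34) beside Pck1 and Fbp2. That call was lost without WT replicate 1 or 3 or Fbp1-deleted replicate 8 (adjusted p between 0.05 and 0.07). Fbp2, which lies beside the edited Fbp1 gene, is among the periportal members that rose.

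Most secreted proteins of the hepatocyte did not pass. Of 26 genes of hepatocyte identity and plasma proteins 2 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.11, adjusted p = 0.084, camera), namely the transcription factors Foxa2, from 33.4 ± 6.50 to 7.64 ± 2.92 CPM, and Cebpa, from 521.5 ± 88.4 to 326.8 ± 76.9 CPM. That list was called lower with library totals (adjusted p = 0.045) and without WT replicate 1 (adjusted p = 0.031). Of 29 xenobiotic cytochrome P450 genes and regulators 8 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.12, adjusted p = 0.076, camera), with Cyp2a5 at -1.85 (SE 0.24) and the nuclear receptor Nr1i3 at -1.07 (SE 0.15). The P450 list was called lower without WT replicate 1 or 2 or Fbp1-deleted replicate 10 (medians -0.20, -0.17 and -0.30, adjusted p between 0.0093 and 0.048, camera). Of 28 glutathione, conjugation and NRF2 genes 4 fell and 2 rose (4 and 2 adjusted over the list alone; median -0.03, adjusted p = 0.79, camera), with Osgin1 at -2.08 (SE 0.28), Gsta3 at -1.03 (SE 0.16), Srxn1 at 1.20 (SE 0.18) and Ephx1 at 0.85 (SE 0.16). Of 24 acute phase genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.26, adjusted p = 0.13, camera), with Apcs at -1.14 (SE 0.18), Orm3 at -1.30 (SE 0.23) and Cebpd at 0.68 (SE 0.18), and the list was called lower without WT replicate 1 (adjusted p = 0.032). Cyp2a5, Gsta3 and Orm3 have close paralogs that could share reads.

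Clock and sex-biased genes were examined because they can move with the hour of collection or the sex of the animals, which the labels do not give. Of 12 clock genes of the Dbp phase 6 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.62, adjusted p = 2e-04 with camera, adjusted p = 0.25 with an estimated correlation), with Per3 at -2.0 (SE 0.28), Usp2 at -1.30 (SE 0.11) and Per2 at -0.62 (SE 0.15). Of 5 genes of the opposite Bmal1 phase 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.49, adjusted p = 0.076, camera), namely Clock at 0.54 (SE 0.14) and Arntl at 1.20 (SE 0.35), and the call of Arntl was lost without WT replicate 2 or 5 or Fbp1-deleted replicate 6, 9 or 10 (adjusted p between 0.0574 and 0.0699). The Bmal1 list was called higher with library totals (adjusted p = 0.046) and without WT replicate 3 or 4 (adjusted p = 0.03 and 0.04). Xist stood between 341.7 and 696 CPM in all 10 libraries (change 0.22, SE 0.21, adjusted p = 0.489), and the Y-linked Kdm5d and Uty were near 1 CPM or below in both groups and did not pass (adjusted p = 0.402 and 0.953). The Y-linked Ddx3y and Eif2s3y, below the filter, had 34 and 28 counts in all WT and 28 and 16 in all Fbp1-deleted libraries. With Xist present in all 10 libraries and Y-linked transcripts near the floor in both groups, these values are those of female animals throughout. They argue against a difference in sex between the groups. Of 22 female-biased genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.96, adjusted p = 0.035 with camera, adjusted p = 0.52 with an estimated correlation), with Acot3 at -2.02 (SE 0.21) and Cux2 at -2.10 (SE 0.34). The list's mean log2 CPM lay between 4.10 and 7.37 in WT and within that range in all 5 Fbp1-deleted libraries (4.38 to 5.71). That list was not called without WT replicate 5 or Fbp1-deleted replicate 8 or 9 (adjusted p between 0.059 and 0.11), with library totals alone (adjusted p = 0.081) or by fry (adjusted p = 0.088). Of 17 male-biased genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Elovl3 at 1.59 (SE 0.28) and Selenbp2 at -1.97 (SE 0.43), a median of -0.14, a mean of 0.05 and no call (adjusted p = 0.34, camera), except without WT replicate 4, where the median was 0.41 and the list was called higher (adjusted p = 0.024).

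Markers of other tissues gave no calls over all 10 libraries with edgeR. Of 7 erythroid markers 0 passed (0 adjusted over the list alone), with Hba-a1 at -0.17 (SE 0.23), and the median of 0.13 and mean of 0.10 stood against a downward camera direction (adjusted p = 0.94). Of 7 mesothelial markers 0 passed (0 adjusted over the list alone; median 0.75, adjusted p = 0.39, camera), with Msln at 2.31 (SE 0.82, adjusted p = 0.0706), which passed without WT replicate 1 (3.18, adjusted p = 0.0319) and with limma-voom (adjusted p = 0.0237). Of the adipocyte, pancreas and muscle markers only Mylpf was measured (-0.48, SE 0.36, adjusted p = 0.375), and that list and the list of sex chromosome transcripts had too few measured members to test. Nothing in the labels marks a batch, and the library numbers run in the order of the groups, so a batch and the genotype cannot be told apart here.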

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

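The tests of the neighbourhood of Fbp2, of transcription running on, of a longer fast and of fewer Kupffer cells were chosen after the results were seen, while the fits with a clock or leukocyte index and the search for sequence shared by Fbp1 and Fbp2 were planned after the data were seen but before their result. Among 428 sets of 5 values (the CPM of 156 named genes, the list means and the library measures, in each group), 32 had 1 library far from the other 4 on Dixon's ratio with a critical value of 0.71. Chance flags about 1 in 20, and 7.5% were found.

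Fbp1-deleted replicate 8 stood apart in 10 sets. In CPM it was low for Dlst (196.5 against 230.2 to 241.6), Srxn1 (34.6 against 63.6 to 71.7) and Ei24 (208 against 303.7 to 321.9), and high for Thy1 (11.2 against 5.35 to 6.75), Col1a1 (37.2 against 4.55 to 9.30), Ccl9 (35.8 against 16.3 to 21.2), Irf7 (20.3 against 13.3 to 14.7) and Per3 (28.5 against 12.7 to 16.1). Its list means were high for fetal and tumour markers (2.11 against 1.76 to 1.85) and for B cell markers (0.79 against -0.25 to 0.04). Fbp1-deleted replicate 10 was apart for Mx2 (1.60 CPM), Egln3 (44.1 CPM) and the mean of amino acid catabolism (8.95), and replicate 9 for Hba-a1 (29.5 CPM).

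Among WT livers, replicate 4 was high in CPM for Onecut1 (103.8 against 23.4 to 30.4), Kynu (124.1), Hsp90b1 (721.8) and Xbp1 (268.9) and low for Acot3 (169.8), and its mean of monocyte and lipid-associated macrophage markers was low (1.95). Replicate 5 was high for Cyp2g1 (22.4 CPM), S1pr5 (20.7 CPM), Cux2 (135.1 CPM) and Col12a1 (2.06 CPM) and low for Nr4a3 (0.0514 CPM). Replicate 1 was high for Kdm5d (1.77 CPM) and low in its means of gluconeogenesis (7.32), glycolysis (5.59) and the tricarboxylic acid cycle (7.03). Replicate 2 had the largest total (23894812 counts), a high Eno1 (731.7 CPM) and a low mean of senescence genes (3.42).

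Fbp2 rose beside the loss of Fbp1. Reads of Fbp1 given to Fbp2 would raise Fbp2 in WT, where Fbp1 was abundant, and not after the loss of Fbp1. The levels alone therefore go against that direction of sharing. For sharing in either direction, 0% of the 1439 words of 31 bases in the annotated Fbp2 transcripts stand in an Fbp1 transcript. That length is Salmon's default, and the longest shared run has 23 bases. A change of the whole neighbourhood was not seen, as 0 of 13 other tested genes within 1 Mb passed with a 2-fold change. Transcription running on from the edited gene into Fbp2, which lies downstream on the same strand, cannot be told apart from a regulated response, since Fbp2 reached 10.1% of the WT Fbp1 level and gene totals do not show reads between the genes. A response of the liver to the missing enzyme stays open as a biological hypothesis.

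Fasting-type genes rose. A longer fast before collection would lower lipogenesis, but the lipogenesis list had a median change of 0.52. A different clock phase cannot be told apart, since the index of clock genes itself varied with genotype (R2 0.61). With that index as covariate the median of the fasting list went from 1.07 (median SE 0.23) to 0.44 (median SE 0.27). In that fit 3 of 14 called members stayed called, and 290 of all genes tested were called. Camera called the list at the preset correlation (adjusted p = 0.0054) but not with an estimated one (adjusted p = 0.31 with an estimated correlation). A response to impaired glucose production, with a normal feeding state, may account for both lists and was not tested.

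Interferon-stimulated genes fell with leukocyte markers. Fewer Kupffer cells alone would not lower them by more than the markers of those cells, but the list's median was -1.02, while the lowest of the called markers, Timd4, named after its value was seen, stood at -0.68 (its call was lost without WT replicate 1, 2, 3 or 5 or Fbp1-deleted replicate 6, 7 or 9, adjusted p between 0.0535 and 0.0954), and 10 called interferon genes lay below it by over 2 SE. Kupffer markers that were not called were left out of that comparison. Fewer leukocytes of all kinds cannot be told apart: with the index of leukocyte markers as covariate the median was -0.49 (median SE 0.61 in place of 0.22) and 0 of 20 calls stayed. The index followed genotype (R2 0.87), and of all genes tested 6 were called in that fit, so the lost calls are not particular to interferon genes, while camera called the list at the preset correlation (adjusted p = 2.5e-05) but not with an estimated one (adjusted p = 0.71 with an estimated correlation). A lower interferon tone in the deleted liver stays open and may go with either.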

How the results depend on the processing

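The fits with a marker index as covariate and the left-out libraries for genes named only in the closing section were chosen after the data were seen, and all other alternatives before. Fbp1 kept its direction and its call in every alternative, with -6.76 to -6.52 when 1 library was left out. A stricter threshold of 0.01 left 678 genes higher and 633 lower, and a test against a fold of 1.5 left 228 and 214, since both ask for more. Leaving out 1 library gave 1066 to 2060 genes higher and 1019 to 1858 lower. Without Fbp1-deleted replicate 9, 1066 were higher, and without replicate 6, 1086 were higher and 1019 lower, from fewer samples. The upper ends came without Fbp1-deleted replicate 8, which lay nearest to WT on the first component. Why single libraries differ in this was not tested. DESeq2 called 1958 higher and 1793 lower, and 3168 of the 3178 calls were among them. With library totals alone 1190 rose and 1965 fell, and with upper quartile scaling 1266 and 1878. The median of all genes was then -0.078 and -0.063, in place of 0.009. No called gene changed sign in any setting. With camera at an estimated correlation 0 lists were higher and 0 lower, in place of 11 and 12 (9 at an unadjusted p under 0.05, while fry called 25), with estimated correlations of up to 0.732, in the unfolded protein response list. Leaving out 1 library gave 9 to 13 lists higher and 9 to 16 lower. For the 244 gene results, 193 of them called, 4839 of 5347 alternative values stayed on their side of the threshold, 430 lost a call, 78 gained one and 0 reversed. For the 51 lists 729 of 812 stayed, 48 lost a call, 35 gained one and 0 reversed. Direction was not compared where neither value passed. Of 156 genes that the report names, 7 lost a call when some library was left out, as did 2 of the 21 tested genes named only in the closing section, Pdk4 and Timd4. At this depth Il6, Tnf and Cdkn2a lay below the filter on low counts.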

Other observations

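The gene families below and their named members were chosen after the data were seen, as was the idea of growth hormone, though its 5 genes were set before their values were seen. The splits of the libraries were set before their counts were seen. Of 14 measured replication-dependent histone genes 7 fell and 0 rose (median -0.80), among them Hist2h2aa2 at -0.91 (SE 0.12) and Hist2h2be at -1.54 (SE 0.34). Several histone genes are near copies, so the values of single members rest on how the reads were divided between them. Of 11 genes of the pyruvate dehydrogenase complex and its regulators 6 rose and 0 fell, with Pdhb at 1.12 (SE 0.10), Pdha1 at 0.51 (SE 0.10) and the inhibitory kinase Pdk4 at 2.92 (SE 0.79). The call of Pdk4 was lost in 8 of the 10 fits that each left out 1 library, all but those without WT replicate 3 (3.59) or Fbp1-deleted replicate 8 (adjusted p between 0.0524 and 0.0786 where lost), and its 185 counts in Fbp1-deleted replicate 8 lay within the WT range of 80 to 416. Of 42 mitochondrial carriers of the Slc25 family 13 rose and 2 fell, led by Slc25a22 at 1.90 (SE 0.20), Slc25a47 at 1.67 (SE 0.19) and Slc25a32 at 1.5 (SE 0.14).

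Some genes of the secretory pathway rose. Of 23 components of COPII coats and the Sec translocon 6 rose and 0 fell, with Sec23a at 0.79 (SE 0.14) and Sec24d at 0.73 (SE 0.19), and of 15 subunits of the signal peptidase, translocon-associated and oligosaccharyltransferase complexes 5 rose and 0 fell, with Ssr3 at 0.73 (SE 0.13). Of 37 proteasome subunits 6 rose and 3 fell, and the ones that fell were the interferon-induced Psmb8 (-0.65), Psmb9 (-1.14) and Psmb10 (-1.12). Of 75 cytosolic ribosomal proteins 0 rose and 2 fell (median -0.15), of 75 mitochondrial ones 6 rose and 0 fell, of 17 vacuolar ATPase subunits 1 rose and 1 fell, and of 327 Zfp genes 25 rose and 19 fell. None of the 10 families passed camera with an estimated correlation (adjusted p between 0.12 and 0.78). The medians of mitochondrial ribosomal (0.03), vacuolar ATPase (0.08) and Zfp genes (0.06) are no larger than the shift that library totals alone give the median of all genes (from 0.009 to -0.078), so they give no direction.

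Lower growth hormone signalling through STAT5 is a hypothesis prompted by the falls of Socs2, Onecut1 and Cux2 and the rise of Lepr. Of 5 further genes of that pathway 4 fell, with a median change of -0.95: Igf1 (-0.68, SE 0.13), Igfals (-1.94, SE 0.26), Cish (-1.81, SE 0.43) and Prlr (-0.95, SE 0.14), while Ghr stood at -0.17 (SE 0.10, adjusted p = 0.257). Bcl6, a repressor of STAT5 targets, rose by 1.57 (SE 0.29). The values are in line with the hypothesis but were found in the same livers, and feeding state, which also moves these genes, was not recorded in the labels.

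Other splits of the 10 libraries did not reach the count of called genes: the real split gave 3178, the highest of the other splits gave 1350, and 1 of 100 splits, the real one, gave as many. With 100 splits no smaller share can be seen, and the splits do not tell a batch apart from the genotype. Chance cannot be excluded for the count of called lists, where the real split gave 23, the highest other split 25, and 5 of 100 splits, the real one included, gave as many. The 4 others exchanged 1 library of each group, so they keep most of the genotype contrast, while the 82 splits that exchanged 2 gave at most 19 lists. Members of a list vary together between livers, so a preset correlation of 0.01 may be too small here, and with estimated correlations 0 lists were called. The counts of single genes within lists do not depend on it.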
